A study of Homo sapiens with 2 samples.

How the data were processed

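RNA of THP-1 cells was hybridised to one-colour Agilent whole-genome expression arrays, 1 array for untreated cells and 1 for cells given ATRA and RAD001. Per the labels' protocols, total RNA was purified on RNeasy columns and Cy3-labelled cRNA was made from 0.5 ug of it with the Quick Amp kit. Per the file headers, the arrays were scanned and the deposited intensity values were extracted by Agilent Feature Extraction, whose version the submitters' processing notes give as 10.5.1.1. Per the file headers, the processed intensity of a spot is background-subtracted and detrended within the array and is not normalised between arrays. The authors also deposited a value table on a linear intensity scale, with medians of 141.45 for untreated cells and 169.2 for ATRA+RAD001. Set against the scanner files, it equals the processed intensity multiplied by 1 constant per array (0.722 and 0.765), and what set these constants is not given in the sources used here. The samples were grouped by the treatment named in their labels.

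Each array held 43376 non-control and 1639 control spots. The 75th percentile of the processed intensity over non-control probes was 2270.1 in untreated cells and 2163.6 with ATRA+RAD001. Spots flagged as outliers (139 and 111) were left out, which removed 68 of 41000 probes. Values were log2 of the processed intensity minus that percentile of the array, and spots of a probe were averaged. The scanner files name probes by accession and hold no gene symbols. RefSeq accessions were matched without versions to a gene table of assembly GRCh38.p14, which named 26187 of the remaining 40932 probes, each with 1 symbol, and left 14745 unnamed. The array design refers to an older human assembly, so no coordinates are given. Of the 17707 genes, 6458 had several probes, and a gene took the value of its brightest probe. Of 4759 genes with several probes well above background on both arrays, the SD of the log2 difference between probes had a median of 0.204, and 9 had 1 probe at least 2-fold higher and another at least 2-fold lower. The SD of log2 signals between the 10 spots of a probe had a median of 0.0496 in untreated cells and 0.0501 with ATRA+RAD001, which is noise within an array and not replicate error. The number of arrays, 1 per group, limits the precision.

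Genes were compared where the chosen probe was well above background on both arrays by the extraction software's flag, and called higher or lower at 2-fold or more. The 450 genes well above background with ATRA+RAD001 only and the 362 in untreated cells only were given a lower bound. The bound sets the bright signal against the higher of the dim array's lowest signal well above background and the probe's own signal there. Of the remaining genes, 3673 were not well above background on either array. Gene lists were summarised by the median log2 difference of their members, set as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins. This describes these arrays and is not a test over replicates.

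The groups, the 2-fold rule, 22 gene lists, most alternatives and the rule for named genes were fixed before the data were examined. That rule took the 12 highest and the 12 lowest genes, the 4 largest bounds in each direction, and up to 4 members of each list by size of difference. It also took list members with a bound of at least 2-fold, and always MTOR, FKBP1A, RARA, RXRA, CYP26A1, CD14, ITGAM and CD38. Some genes that the rule takes are not reported here. The lists covered retinoid response, myeloid maturation and its transcription factors, granules, the NADPH oxidase, HOX and MLL-associated genes, cell cycle, translation, ribosome assembly, lipid, glucose and amino acid metabolism, lysosomes, interferon, cytokines, antigen presentation, apoptosis, mTOR components, reference genes and other cell types.

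Alternatives were normexp background correction (offset 50), quantile, median and cyclic loess scaling, the authors' value table, the median over probes, other filters on dim probes, a 3-fold rule and another detection flag. Normexp was planned on mean spot intensities, which the scanner files lack, and was run on median spot and background intensities. Centring on 8 spike-in probes, whose median log2 difference was -0.16, was added after seeing the data. Computations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. The procedure was tested on simulated data for the comparison of untreated cells with ATRA+RAD001, over 13375 genes. All 50 genes planted at each log2 change of 1.5, -1.5, 3.0 and -3.0 were called (100.0%), as were 0.0% of 13175 others. Simulated treated values were the untreated values plus noise with an SD of 0.204, and genes were planted only above the median untreated signal. The simulation held no variation between cultures or slides, so the 0.0% is not a false-call rate of the 2-fold rule on real arrays. Of 200 random lists of 25 genes, 5.5% lay outside the central 95%. A share of about this size follows from how the lists were drawn, and lists of genes that vary together were not simulated.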

Results

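The series measured the transcriptome of THP-1, a human acute monocytic leukaemia cell line grown in suspension. Untreated cells were set against cells given all-trans retinoic acid (ATRA), a ligand of the retinoic acid receptors, together with RAD001 (everolimus), an inhibitor of the mTOR kinase. The labels give the ATRA concentration as 1 mM and the RAD001 concentration as 2.5 nM, and RNA was taken at 5 days. The unit of the ATRA concentration is uncertain and is printed as the labels give it. Each group had 1 one-colour (Cy3) Agilent array, so no difference has a replicate check, and no test between the groups, p-value or standard error is given. ATRA alone and RAD001 alone, which the labels also mention, were not analysed here, so no difference can be assigned to either compound. The arrays were on different slides, and slide and group cannot be told apart. Each array carried 45015 spots, 43376 of them for 41000 non-control probes, of which 40932 remained after outlier-flagged spots were left out. Of these, the number of probes well above background was 28566 (69.79%) in untreated cells and 28573 (69.81%) with ATRA+RAD001, and no spot was saturated. Of 17707 named genes, 13210 were well above background on both arrays. Across these genes the log2 signals of the arrays correlated at 0.959, where genes are not independent replicates.

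The comparison asked how 5 days of ATRA+RAD001 altered gene expression in THP-1 cells. The cells given ATRA+RAD001 had higher signals for 14 of 22 measured retinoid-responsive genes, 9 of 12 neutrophil and secondary granule genes and 13 of 22 cytokines and chemokines. They had lower signals for 6 of 11 primary granule and progenitor genes, led by the cathepsin G and myeloperoxidase genes. Those 6 were MYB and the granule genes CTSG, MPO, ELANE, AZU1 and PRTN3. Each of these counts is by a 2-fold rule. The 12 neutrophil and secondary granule genes leave out LTF, LCN2, MMP8, CEACAM8, PGLYRP1 and OLFM4. These secondary granule genes were not well above background on either array. By the fixed size rule, 1410 genes (10.7% of 13210) were at least 2-fold higher and 752 (5.7%) at least 2-fold lower with ATRA+RAD001. Higher genes thus made up 65.2% of those at least 2-fold apart. That share depended on the scaling, with 1084 higher and 923 lower genes (54.0% higher) after quantile normalization. It was 1800 higher and 512 lower (77.9% higher) when the arrays were centred on their spike-in controls, which moved the median of all genes by 0.158 on the log2 scale. A further 279 genes were well above background with ATRA+RAD001 only and 120 in untreated cells only, each with a lower bound of at least 2-fold. These counts were 104 and 33 under the normexp background model, and 192 and 183 after quantile normalization.

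**Figure D1:**
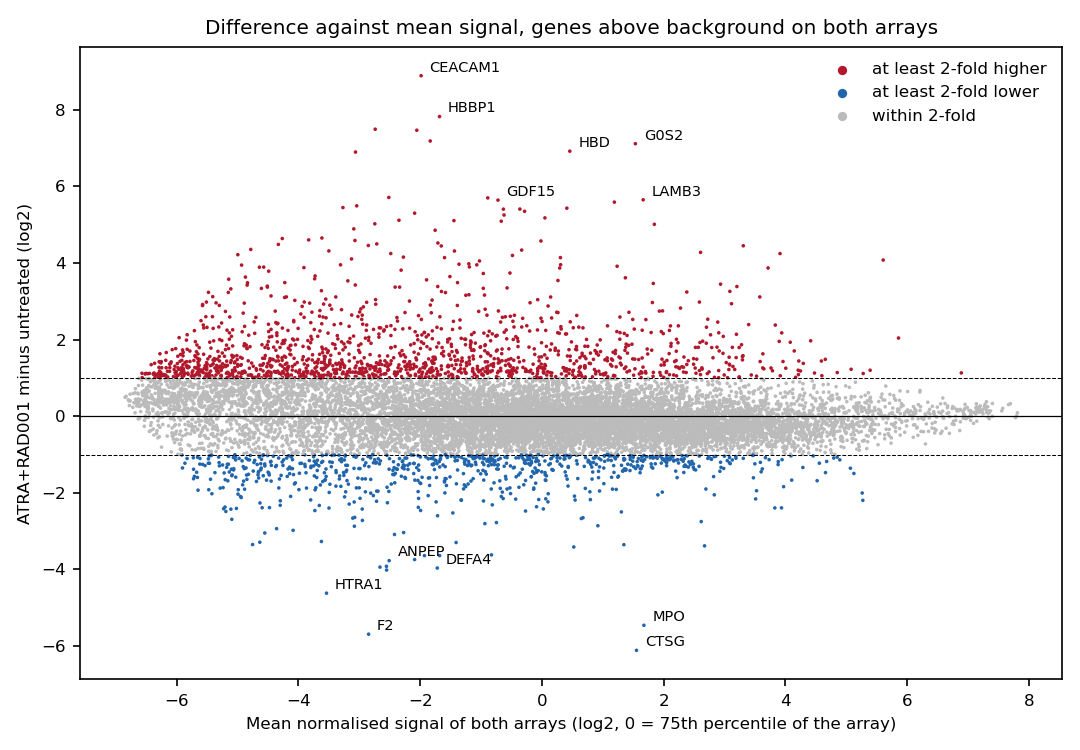
Each point is 1 of 13210 genes well above background on both arrays, with the mean normalised log2 signal of both arrays on the x axis and the log2 difference, ATRA+RAD001 minus untreated, on the y axis. Dashed lines mark 2-fold, with 1410 genes at or above the upper line in red and 752 at or below the lower line in blue, and genes within 2-fold are grey.

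Among genes well above background on both arrays, the largest differences upward began with CEACAM1 (probe A_24_P382319), a cell adhesion molecule of granulocytes, at 473-fold. Its other probes were well above background with ATRA+RAD001 only. The beta-like globin pseudogene HBBP1 was 226-fold higher, and TGM2, the tissue transglutaminase, was 180-fold higher. They were followed by the inhibitory leukocyte receptor gene LILRB2 (177-fold), RETREG1 (145-fold), a receptor for autophagy of the endoplasmic reticulum, and G0S2 (138-fold), an inhibitor of adipose triglyceride lipase. HBD, the delta-globin gene, was 121-fold higher, with log2 differences of 6.20 and 6.92 on its probes. EXTL1 was 119-fold higher, and CYP27A1, the sterol 27-hydroxylase, 52.4-fold. The chemokine gene CCL4 (51.9-fold), the laminin gene LAMB3 (50.2-fold) and the TGF-beta family gene GDF15 (49.9-fold) completed the 12 highest. HBD and HBBP1, CCL4, CEACAM1 and LILRB2 belong to families of similar sequence whose probes can share signal. The second probes of TGM2 and RETREG1 were well above background with ATRA+RAD001 only. CYP26A1 (probe A_23_P138655), the retinoic acid hydroxylase and a standard retinoid target, was well above background with ATRA+RAD001 only, at least 978-fold higher. The same held for the prostaglandin E synthase gene PTGES (at least 226-fold), HIC1 (at least 173-fold) and LILRA5 (at least 80.4-fold).

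The 12 lowest genes among those well above background on both arrays included CTSG, MPO and DEFA4, which encode proteins of primary (azurophilic) granules. CTSG (probe A_23_P140384), cathepsin G, was 69.1-fold lower with ATRA+RAD001, and MPO, myeloperoxidase, was 43.9-fold lower. F2, prothrombin, was 51.6-fold lower by 1 probe, while its other probe was not well above background on either array, and the serine protease gene HTRA1 24.6-fold lower. The defensin gene DEFA4 was 15.6-fold lower, TGFB2 15.3-fold, and ANPEP, the myeloid surface aminopeptidase CD13, 13.6-fold. VCX (16.2-fold), VCX2 (15.1-fold) and VCX3A (13.4-fold) are near-identical copies whose probes can share signal, and the VCX2 probes differed, at -3.92 and -1.30. SLC35F1 and CILP2 were 12.5-fold and 12.4-fold lower. Among genes well above background in untreated cells only, SFRP5 was at least 33.2-fold lower, SERPINB10 at least 25.4-fold, EPX, eosinophil peroxidase, at least 16.1-fold, and F7, coagulation factor VII, at least 14.9-fold.

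**Figure D2:**
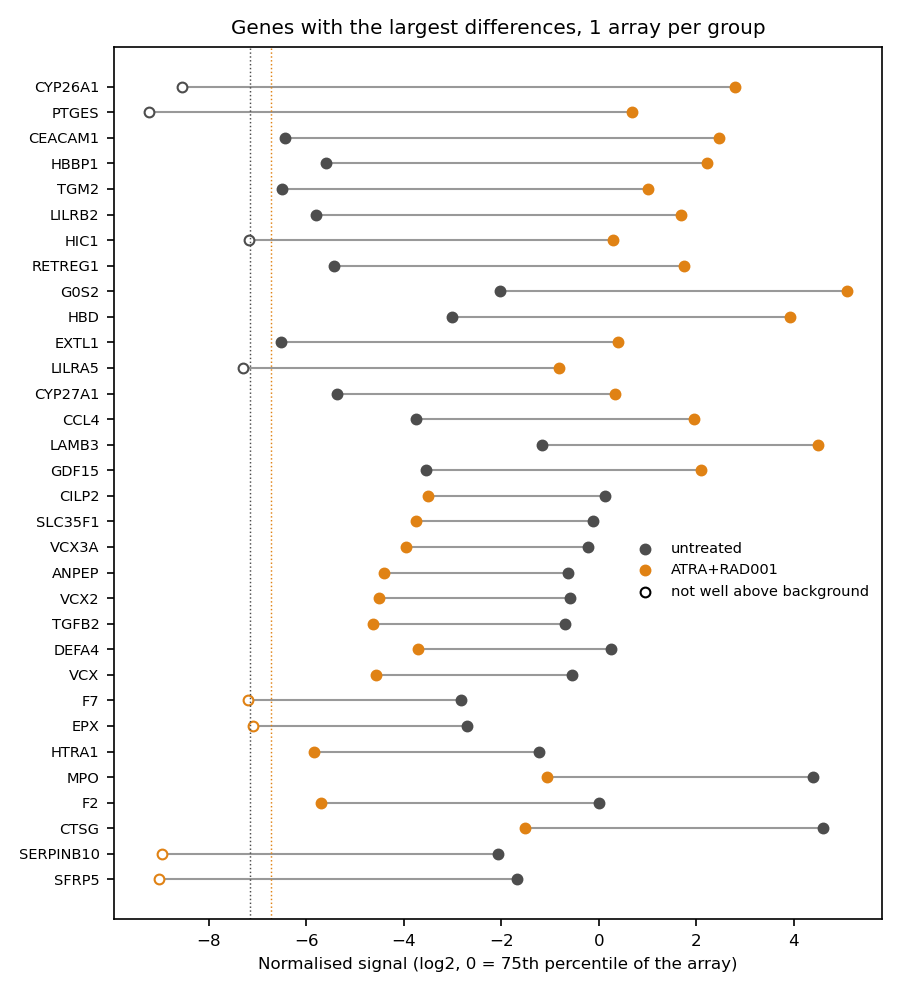
Normalised log2 signal (0 is the 75th percentile of the array) in untreated cells (grey) and with ATRA+RAD001 (orange) for the 12 highest genes, the 12 lowest and the 4 with the largest bounds in each direction, 1 array per group. Open circles are signals not well above background, and dotted lines mark the lowest signal well above background on each array, -7.14 in untreated cells and -6.72 with ATRA+RAD001.

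Folds against a signal near background depended on the background model. With the normexp model the fold was 132 for CEACAM1, 100.2 for HBBP1, 70.6 for LILRB2, 68.7 for RETREG1, 35.7 for EXTL1 and 25.3 for CYP27A1. The corresponding folds downward were 20.4 for F2, 10.1 for HTRA1, 9.30 for VCX, 8.75 for TGFB2, 8.57 for VCX2 and 8.78 for ANPEP. TGM2 had no such fold, because its brighter probe under that model was well above background with ATRA+RAD001 only. The lower bounds became 219-fold for CYP26A1, 51.3-fold for PTGES, 31.6-fold for HIC1, 28.0-fold for LILRA5, 11.0-fold for SFRP5, 8.11-fold for SERPINB10, 4.37-fold for EPX and 4.15-fold for F7. CTSG (67.6-fold lower) and MPO (46.3-fold lower) moved by less than 1.5 times.

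Of the 22 retinoid-responsive genes measured on both arrays, 14 were at least 2-fold higher with ATRA+RAD001 and 2 lower. The chemokine gene CCL2 was 32.2-fold higher, ASB2, a ubiquitin ligase subunit, 17.6-fold, and the adhesion molecule gene ICAM1 12.5-fold. The list's median log2 difference of 1.51 lay above those of all 10000 random gene lists of the same size matched on mean expression. CRABP2 (at least 23.7-fold) and RARB (at least 17.4-fold) were well above background with ATRA+RAD001 only, and the median with such genes at their bounds was 1.80. Under normexp the bounds were 6.36-fold and 4.92-fold. Retinoid receptor genes differed in direction. RARG had a log2 difference of 1.46. RXRA was 3.95-fold lower, with probes at -1.98 and -1.10. RARA was 1.32-fold higher by its brighter probe, at 0.40, while its other probe was at 1.45. CD38, a surface enzyme that retinoids are known to induce in myeloid cells, was 3.25-fold higher.

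Of 20 monocyte and macrophage markers, 9 were at least 2-fold higher and 3 lower, with a median log2 difference of 0.80 (99.98th percentile of the random lists). Over the 12 markers above the array median on both arrays it was 1.44. That filter removed members of both directions, among them the lower MARCO and FCN1 and the higher CD86 and CD163. The integrin genes ITGAX (20.2-fold) and ITGAM (12.2-fold) and the scavenger receptor gene CD36 (15.8-fold) were higher. MARCO, another scavenger receptor gene, was 9.77-fold lower (3.35-fold under normexp), and FCN1 and LYZ were the other members at least 2-fold lower. CD14 was 1.81-fold higher, below the 2-fold rule. Of 12 neutrophil and secondary granule genes, 9 were at least 2-fold higher and 0 lower, and the median of 2.24 lay above all random lists. The secondary granule genes LTF, LCN2, MMP8, CEACAM8, PGLYRP1 and OLFM4 were not well above background on either array. TCN1 was well above background in untreated cells only, with a bound under 2-fold, and without the filter on dim probes the median over 21 members was 0.63 (99.94th percentile). Besides CEACAM1, the 9 higher genes included the gelatinase gene MMP9 (19.0-fold), the cathelicidin gene CAMP (15.5-fold) and the formyl peptide receptor gene FPR1 (9.55-fold). Of the 6 subunits of the phagocyte NADPH oxidase, 3 were at least 2-fold higher and 0 lower, among them NCF1 (14.6-fold) and CYBB (3.78-fold), and NCF4 was 1.67-fold higher. Their median was 1.24, above all random lists. NCF1 has near-identical pseudogenes that can share its signal.

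Of 11 primary granule and progenitor genes, 6 were at least 2-fold lower and 2 higher, and the median of -1.49 lay below all random lists. With CTSG and MPO, the neutrophil elastase gene ELANE was 4.58-fold lower, AZU1 4.15-fold and the progenitor transcription factor gene MYB 2.82-fold. The granule gene PRTN3 was the other lower member. The remaining measured members had positive log2 differences: FLT3 0.24, IGLL1 0.33, SPINK2 0.77, CD93 1.16 and CSF3R 1.97. The lower members were thus granule genes and MYB. The progenitor genes KIT, CD34 and PROM1 were not measured on both arrays, so the direction of progenitor genes as a group cannot be told. SPINK2 (-6.82 untreated, -6.05 with ATRA+RAD001) and CD93 (-6.22 and -5.06) had signals near the lowest well above background (-7.14 and -6.72). Without the filter on dim probes the list's median was 0.20. Among 16 HOX and MLL-fusion-associated genes, 2 were at least 2-fold higher and 2 lower, with a median of 0.22 (96.86th percentile). This percentile lay outside the central 95% under quantile normalization (98.27th), cyclic loess (98.08th) and the median over probes (99.26th). MYC was 2.19-fold lower (within 2-fold under spike-in scaling), while EYA1 (2.14-fold) and HOXA4 (2.05-fold) were higher, both under 2-fold with normexp. Of 25 myeloid transcription factor genes, 6 were at least 2-fold higher and 3 lower, with a median of 0.35 (99.7th percentile). BHLHE40 was 4.03-fold higher, ID2 4.01-fold and EGR2 3.78-fold (2.29-fold under normexp). EGR3 was well above background with ATRA+RAD001 only, at least 9.38-fold higher (3.0-fold under normexp).

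Most differences among the mitotic and DNA replication genes were within 2-fold. Of 33 genes, 2 were at least 2-fold lower and 0 higher, and the median of -0.56 (1.47-fold lower) lay below all random lists, while MKI67 was at 0.05. The replication licensing gene CDC6 was 2.23-fold lower and MCM4 2.07-fold, while GINS2 (1.99-fold) and E2F1 (1.80-fold) lay within 2-fold. MCM4 lay within 2-fold under normexp, and both CDC6 and MCM4 did so under spike-in scaling. Among 17 CDK inhibitor and cyclin D genes, 4 were at least 2-fold higher and 2 lower, with a median of 0.16 (94.98th percentile) that turned to -0.03 when probes of a gene were combined by their median. The antiproliferative gene BTG2 was 13.2-fold higher, CDKN1C 2.53-fold lower, CDKN2A 2.50-fold higher and CCND1 2.26-fold higher, the last pair within 2-fold under normexp. Of 26 apoptosis regulators, 4 were at least 2-fold higher and 2 lower, with a median of 0.10 (93.1st percentile, but 98.89th under normexp and 99.69th among genes above the array median). BMF, a pro-apoptotic BH3-only gene, was 11.7-fold higher and BIRC3 3.12-fold, whereas BCL2 was 3.01-fold and FAS 2.80-fold lower.

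Genes of ribosome assembly and of the ribosome itself differed. Of 25 ribosome biogenesis genes, 5 were at least 2-fold lower and 0 higher, and the median of -0.57 (1.49-fold lower) lay below all random lists. UTP20 was 2.84-fold lower, MRTO4 2.56-fold, NIP7 2.45-fold and BOP1 2.31-fold. All 52 ribosomal protein and translation factor genes lay within 2-fold, with a median of 0.13 (99.88th percentile) that was 0.00 after quantile normalization. Among random lists not matched on expression it lay at the 94.57th percentile, inside the central 95%. RPL7 was 1.39-fold, RPS6 1.26-fold and RPS25 1.24-fold higher, and EIF4B was 1.29-fold lower, with its probes from -0.67 to 0.03. Ribosomal protein genes have many processed pseudogenes that can share their signal.

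Of 25 cholesterol and fatty acid synthesis genes, 7 were at least 2-fold lower and 0 higher, and the median of -0.76 (1.70-fold lower) lay below all random lists. INSIG1, a regulator of sterol synthesis, was 3.09-fold lower, HMGCS1 2.50-fold, FADS1 2.48-fold and the lanosterol synthase gene LSS 2.46-fold. FADS1 lay within 2-fold when its probes were combined by their median. Of 23 amino acid response and stress genes, 5 were at least 2-fold lower and 0 higher, with a median of -0.52 (0.02nd percentile). Members went both ways, with 7 above the median of all genes. CHAC1 (0.68), SESN2 (0.57) and DDIT3 (0.41) had positive log2 differences, while TRIB3 (-0.52) and ATF4 (-0.36) had negative ones. VLDLR was 3.69-fold lower, the amino acid transporter gene SLC7A5 2.88-fold and PHGDH, the first enzyme of serine synthesis, 2.74-fold. STC2 was 2.52-fold lower (1.47-fold under normexp). The 27 glycolysis and hypoxia-responsive genes had a median of -0.11 (29.82nd percentile) and a mean of 0.20, which differ in sign, and the median was 0.05 under spike-in scaling. Among these genes 3 were at least 2-fold higher and 0 lower. These were the glucose transporter gene SLC2A3 (6.97-fold), EGLN3 (5.51-fold, 2.46-fold under normexp) and ADM (4.15-fold, 1.72-fold under normexp), and HK1 was 1.95-fold higher.

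The genes of everolimus's target and binding protein lay within 2-fold. MTOR was 1.34-fold lower and FKBP1A, which encodes the everolimus-binding protein FKBP12, 1.04-fold lower, and the log2 difference of FKBP1A was 0.04 under cyclic loess and 0.10 under spike-in scaling. Of 30 mTOR pathway components, 2 were at least 2-fold higher and 2 lower, with a median of -0.18 (22.16th percentile). The translation repressor gene EIF4EBP1 was 2.41-fold lower and IRS2 2.04-fold lower, while SGK1 (2.31-fold) and the mTOR inhibitor gene DEPTOR (2.08-fold) were higher. Under normexp the last 3 lay within 2-fold. Of 34 lysosome and autophagy genes, 8 were at least 2-fold higher and 0 lower, with a median of 0.31 (99.99th percentile). Of these genes, 22 lay above the median of all genes, while others such as ULK1 (-0.25), ATG7 (-0.23) and CTSL (-0.77) had negative log2 differences. TFEB, a transcription factor of lysosomal genes, was 5.52-fold higher, WIPI1 2.74-fold, NPC2 2.69-fold and GABARAPL1 2.64-fold.

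Immune gene lists had medians above 0. Of 22 cytokines and chemokines, 13 were at least 2-fold higher and 0 lower, and the median of 1.24 lay above all random lists. Beside CCL4 and CCL2, LTB was 19.4-fold higher and CCL23 5.98-fold, although the CCL23 probes were at 0.18 and 2.58 and its fold was 2.65 under normexp. IL10 (at least 9.07-fold), CCL22 (at least 7.29-fold) and IL1A (at least 6.89-fold) were well above background with ATRA+RAD001 only, with bounds of 2.76-fold, 2.56-fold and 2.37-fold under normexp. Of 20 antigen presentation genes, 10 were at least 2-fold higher and 0 lower, and the median of 0.93 lay above all random lists. HLA-DMB was 40.7-fold higher, the immunoproteasome gene PSMB9 4.62-fold, HLA-DRA 2.99-fold (1.91-fold under normexp) and CD74 2.72-fold. HLA-DPA1 and HLA-DPB1 had bounds of 2.63-fold and 2.72-fold, and 1.39-fold and 1.44-fold under normexp. Of 35 interferon-stimulated genes, 13 were at least 2-fold higher and 5 lower, and the median of 0.80 lay above all random lists. Over the 28 of them above the array median on both arrays, the median was 0.32 (99.65th percentile). TRIM22 was 6.06-fold higher (2.37-fold under normexp), the transcription factor gene IRF1 5.55-fold, CXCL10 5.29-fold and SAMHD1 4.93-fold. GBP1 was at least 7.39-fold higher (2.39-fold under normexp). HLA genes also resemble each other in sequence. The 5 lower interferon-stimulated genes were IFIT2, IFIT1, OASL, IFI44 and HERC5, named after their values were seen.

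Markers of other cell types were also higher in places. Of 11 such genes measured on both arrays, 5 were at least 2-fold higher and 1 lower, with a median of 0.60 (94.27th percentile, and 99.13th among random lists not matched on expression). ALAS2, the erythroid haem synthesis gene, was 24.9-fold higher (7.62-fold under normexp), LCK 4.70-fold (1.91-fold under normexp) and GP9 3.22-fold, and EPCAM was 3.42-fold lower (2.26-fold under normexp). Well above background with ATRA+RAD001 only were HBG1 (at least 14.3-fold), HBB (at least 12.6-fold), COL1A2 (at least 3.69-fold), PF4 (at least 2.50-fold) and CDH1 (at least 2.36-fold). Under normexp these bounds were 4.40-fold, 3.76-fold, 1.80-fold, 1.34-fold and 1.41-fold. All 14 reference genes lay within 2-fold, with a median of -0.04 (67.27th percentile) that had the opposite sign under cyclic loess and spike-in scaling. TFRC was 1.68-fold, PGK1 1.67-fold and SDHA 1.45-fold lower, and B2M was 1.42-fold higher.

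**Figure D3:**
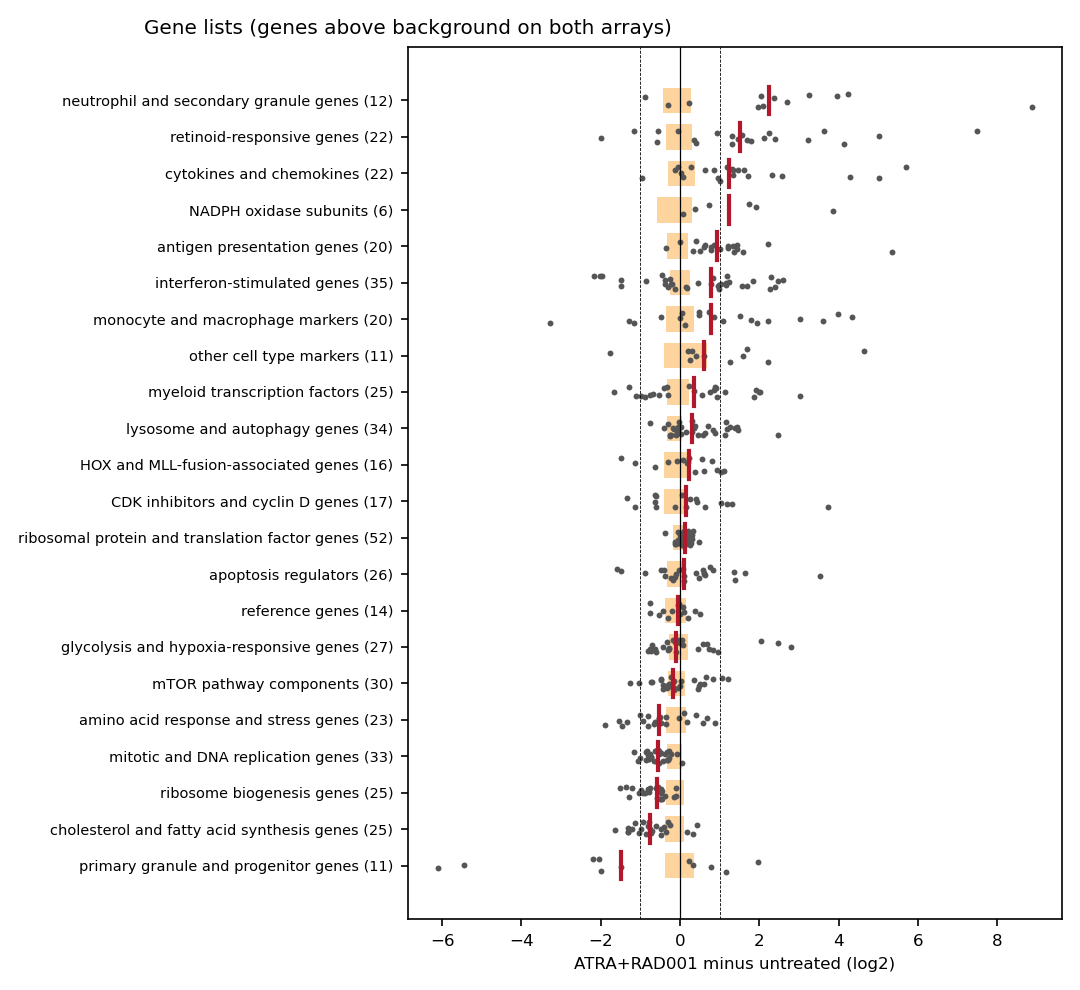
Log2 difference, ATRA+RAD001 minus untreated, of each member (points) of the 22 gene lists measured on both arrays, with the number measured in brackets and list medians as red bars. Orange bands are a normal approximation to the central 95% of the medians of 10000 matched random lists, from their median and SD. Medians ran from -1.49 for primary granule and progenitor genes to 2.24 for neutrophil and secondary granule genes, and 15 of the 22 lay outside their band.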

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

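The test of signal near background in interferon-stimulated genes and the panels of interferon genes were chosen only after the result was seen, as was a rule for the globin test, and the rule for the test of a single scale factor was altered after its value was known. Probes without a gene symbol stood outside the comparison of named genes and were picked out because they carried signal on the ATRA+RAD001 array above that in untreated cells. Of 7983 such probes well above background on both arrays, 1237 (15.5%) were at least 2-fold higher and 228 (2.9%) at least 2-fold lower. Another 477 were well above background with ATRA+RAD001 only, against 459 in untreated cells only.

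The excess of higher over lower signals, among named genes and unnamed probes, was weighed against signal near background, scaling and signal that does not come from mRNA. For unnamed probes, the scalings tried are argued against as the whole cause. At least 68.2% of those at least 2-fold apart were higher under each of 6 alternatives for scaling, background or source of the values. The share was 84.4% by the main values and was lowest, at 68.2%, under quantile normalization. A larger constant shift was not tried for unnamed probes, so a single scale factor stays open there. For named genes scaling also stays open, because lowering the ATRA+RAD001 values by 0.154 would equalise the counts. The scalings tried lowered them by up to 0.064 or, with spike-in controls, raised them by 0.158. By the original size rule alone this would have counted for scaling. A low-signal offset stays open too, since 55.4% (95% Wilson interval 51.4 to 59.3, for counting error over genes that are not independent) of the genes at least 2-fold apart were higher in the brighter part of the genes against 69.1% in the dimmer part, and named probes matched on signal were higher in 12.1% and lower in 6.6%, against 15.5% and 2.9% of unnamed probes. Olfactory receptor genes are mostly silent in blood cells and have a single coding exon. The 31 well above background on both arrays had a median of 0.79. This was the 99.4th percentile of matched lists, whose typical median was 0.39 (under normexp 0.34, at the 98.0th). Signal such as genomic DNA on the ATRA+RAD001 array was predicted to give such a percentile. Of 117 olfactory receptor genes with a probe, however, 45 were well above background with ATRA+RAD001 and 35 in untreated cells. The median thus covers only the detected genes. The keratin-associated and G protein-coupled receptor families had been seen to be high before this test was written, and an effect of treatment or slide remains untested.

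The globin genes HBD and HBBP1 were among the 12 highest, and HBB, HBG1 and HBE1 (at least 2.25-fold) were above background with ATRA+RAD001 only. RNA of erythroid cells is argued against, since 1 of 19 non-globin erythroid genes was at least 2-fold higher (SLC4A1, log2 difference 1.47), 2 were lower, and AHSP, RHAG and HEMGN were not above background on either array, although ALAS2, left out of that panel because its value had been seen, was 24.9-fold higher. Of 5 alpha-like globin genes with a probe, 0 were at least 2-fold higher (HBA1 0.14, HBA2 -1.79), so signal shared between similar beta-like probes and a difference at the beta-globin locus cannot be told apart.

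Interferon-stimulated genes went both ways, with 13 at least 2-fold higher and 5 lower. Signal near background is argued against for IFIT1, IFIT2, HERC5 and OASL, since these 4 of the 5 lower members stayed at least 2-fold lower under normexp (log2 differences from -2.08 to -1.40), and it stays open for IFI44, at -0.75 under normexp and 1.49 log2 units above the lowest signal well above background with ATRA+RAD001. IRF1-associated genes had a median of 1.43, with 12 of 17 at least 2-fold higher and 0 lower (100.0th percentile). A panel of IFIT, OAS, MX and other interferon genes, such as ISG15 and USP18, had a median of 0.01, with 5 higher and 5 lower of 20. The latter median lay at the 50.5th percentile, so the direction of that panel as a set cannot be told. Its 5 higher members were OAS1 (1.05), OAS3 (1.16), MX2 (1.23), IFIT5 (1.57) and RSAD2 (1.85). Its 5 lower members were IFIT1, IFIT2, OASL, IFI44 and HERC5, so the IFIT and OAS genes themselves went both ways. The panels overlap the genes that prompted them.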

How the results depend on the processing

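The spike-in scaling was chosen after seeing the data. Counts of genes at least 2-fold apart stayed within 1.5 times the main counts under normexp (955 higher, 584 lower), quantile, median and cyclic loess scaling, the authors' value table, the median over probes and spike-in scaling. Without the filter on dim probes, 2262 of 17707 genes were higher. Among 10625 genes above the array median on both arrays, 765 were higher and 497 lower, and at 3-fold 547 and 213, where fewer genes can pass by construction. Genes above background on 1 array only with a bound of at least 2-fold numbered 104 with ATRA+RAD001 (279 in the main values) and 33 in untreated cells (120) under normexp, and 192 and 183 after quantile normalization; the cause was not tested. The median of primary granule and progenitor genes was 0.198 without the filter (-1.49 with it), where members below background on both arrays enter. Of the 22 list medians, 15 lay outside the central 95% of random lists, and 14 to 16 under the alternatives. Of 96 named genes at least 2-fold apart on both arrays, 89 to 96 stayed so in the same direction under the other scalings, the median over probes or the authors' table, and 83 of 95 under normexp. For 46 of 134 named genes the main fold exceeded 1.5 times the normexp fold, so signal over background limits the sizes of folds of dim genes. No saturated probe existed to leave out. No paired analysis was possible because each group had 1 array and no test was run.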

Other observations

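The families described here were chosen after their values were seen, by grouping genes on the letters that open their symbols, which also takes in some unrelated genes. Mitochondrial ribosomal protein genes (MRPL symbols) were lower as a group, with a median log2 difference of -0.48 over 50 genes, although 0 were at least 2-fold lower. Genes with MCM symbols had a median of -0.84 over 11 genes, and the 3 at least 2-fold lower were MCM4, MCM10 and the antisense RNA MCM3AP-AS1, of which MCM4 alone encodes a subunit of the replicative helicase. RNA polymerase subunit genes (POLR) had a median of -0.46 over 31 genes. CCL chemokine genes had a median of 1.33 over 11 genes, 8 of them at least 2-fold higher, and keratin-associated protein genes (KRTAP), which hair follicles express, 1.03 over 14 genes with 7 higher and 1 lower. Genes with RPL and RPS symbols, mostly ribosomal protein genes, had medians of 0.16 over 61 and 0.17 over 43 genes. Of 213 families with 8 or more members, 4 lay in the highest and 3 in the lowest 0.1% of matched random lists. If members of a family varied independently, 0.43 families would be expected beyond either limit. That independence was not tested, so the figure does not measure an effect of treatment. None of these 7 medians turned sign under the scaling, background, source and probe alternatives.

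Unnamed probes known only by an array identifier were at least 2-fold higher in 18.0% of 3379 cases and lower in 2.43%, while those with an unmatched RefSeq mRNA accession were higher in 9.9% of 433 and lower in 6.0%.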
